A study of Mus musculus with 7 samples.

How the data were processed

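Messenger RNA from the inguinal white adipose tissue of C57BL/6 mice was sequenced in 7 libraries, 4 from wild-type (WT) animals and 3 from animals labelled as Tm4sf5 knockouts (KO). Inguinal white adipose tissue is the subcutaneous fat pad of the groin, which in mice also encloses a lymph node and lies against muscle and skin. All animals ate standard chow and were untreated, per the labels. RNA was extracted with Trizol and libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA), per the labels' protocols. The design text speaks of 3 biological replicates per condition, while the labels list 4 WT and 3 KO samples. All 7 were used. The labels give no sex, age, litter, batch or day, nor which part of Tm4sf5 was deleted.

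The deposited table held raw read counts per gene for the 7 libraries, as whole numbers for 29517 Entrez gene identifiers. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20.0, reads were trimmed with Trimmomatic and aligned with HISAT2 2.1.0 to mm10, transcripts were quantified with StringTie 1.3.4d, and DESeq2 was used. The annotation, the counting rule and the strand setting are not given in the sources used here. Counts of genes that overlap another gene, or that have close paralogs or pseudogenes (glycolytic enzymes, immunoglobulin and Oas genes, mitochondrial genes with nuclear copies), therefore carry an unknown share of reads from the other copy. No other column of per-sample values was present.

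Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents. Of the 29517 identifiers, 29444 matched and 73 did not, and the unmatched ones held between 0.059% and 0.162% of a library's counts. Library totals ran from 49775077 to 60241436 counts, and 840 genes had no count in any library. A count of 0 was read against a floor of 3 counts, which covers counting error only.

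Counts were analysed in R 4.3.3. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10), which left 19185, and libraries were scaled by the trimmed mean of M values (TMM). KO was compared with WT by edgeR's quasi-likelihood F-test with no covariate, with Benjamini-Hochberg adjustment at 0.05 and, for a further count, at least a 2-fold change. Standard errors of log2 fold changes were computed from the F statistic. CPM values are counts divided by the TMM-scaled library size, on the usual CPM scale, except in the check of sex-linked genes, which used total counts. The replicates were described as biological in the design text, so p-values measure the spread between these samples.

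The design, 26 gene lists and most of the alternative settings were fixed before the data were examined. Of these lists 24 were tested with camera of limma 3.58.1, two-sided, on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and 2 were only looked at gene by gene. Each list was also tested with an estimated correlation, with fry, and by an exact permutation test of its score, which is the mean log2 CPM of its members in each library. The exact test is two-sided over the 35 splits of 7 libraries into 4 and 3, so its smallest possible p is 0.0286. Members of a list were counted as higher or lower after Benjamini-Hochberg adjustment over the list alone, and the count after adjustment over all genes is given beside it. Some genes belong to several lists.

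The genes named in the text were chosen by a fixed rule. Tm4sf5 came first. The rule then took up to 10 genes in each direction with the largest change among genes past an adjusted p of 0.05, with a mean CPM of at least 1, no overlap between the groups and no provisional symbol. It also took up to 4 members of each list with the smallest p. No gene passed the adjusted threshold, so only Tm4sf5 and list members were named by it. Some members that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen, and other list members are named to show what passed or did not pass.

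The edgeR script was tested on simulated counts for the KO and WT comparison, made from the real means and library sizes of 19185 genes with 100 genes changed 2-fold and 100 changed 4-fold. A list of 25 further genes was raised by a log2 shift of 0.8. At an adjusted p of 0.05 edgeR recovered 8% of the 2-fold and 56% of the 4-fold changes, and 1 of its 67 calls was an unchanged gene. On the same counts limma-voom recovered 5% and 56%, with 2 unchanged genes among 63 calls. DESeq2 1.42.0 recovered 35% and 80%, with 53 unchanged genes among 173 calls.

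Libraries were compared by the correlation of log2 CPM and by a chi-square test of counts. The correlation lay between 0.925 and 0.977, and the chi-square per degree of freedom between 105 and 548, so no pair of libraries agreed within sampling noise. Alternatives tried were DESeq2-type size factors, scaling by total counts alone, other filters on low counts, each library left out in turn, replicate numbers as a block, DESeq2, limma-voom, and other forms of the list test. The exact permutation test of the lists, a correction for transcript length and GC content, the omission of WT 2 and WT 4 together, 8 further gene lists, the count of genes at an unadjusted p and its use around Tm4sf5 were added after the data were seen. Values in FPKM or TPM and a comparison table of the authors' own were not used here, so the alternatives planned for them were not run.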

Results

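The series asked how loss of TM4SF5, a transmembrane protein of the 4-pass L6 family, changes the transcriptome of mouse inguinal white fat. Read counts per gene were compared between 4 WT and 3 KO libraries. Libraries are named by their labels, so that KO 3 stands for the library labelled KO replicate 3. Totals were 58197116, 57067052, 60241436 and 55717495 counts in WT 1 to WT 4, and 49775077, 50704542 and 50429520 counts in KO 1 to KO 3. By principal components, KO 1 lay farthest from the other libraries on the first axis, which held 35.7% of the variance.

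Tm4sf5, the targeted gene, was barely expressed in this tissue. Its 4 WT libraries held 33, 45, 47 and 20 counts, and its 3 KO libraries held 7, 6 and 17. These amount to 0.567 ± 0.182 CPM in WT (SD, n = 4) and 0.221 ± 0.117 CPM in KO (SD, n = 3). The log2 fold change of KO over WT was -1.35 (SE 0.50), and it did not pass the adjustment over all genes (edgeR adjusted p = 0.177). The gene (Entrez 75604) is protein-coding and lies on chromosome 11 of mm10, from 70505274 to 70511183. KO 3, at 0.353 CPM, lay above WT 4, at 0.323 CPM, so these counts do not separate the labelled genotypes (exact permutation p = 0.0857, two-sided). Counts this low leave wide counting error, and reads outside a deleted part of the gene would still be counted. A partial deletion was not tested. With the labels of KO 3 and WT 4 exchanged, 868 genes had an unadjusted p under 0.05, against 4187 as labelled. A larger count alone does not show which labels are right, so a mislabelled library was not excluded.

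A predicted gene, Gm30783, separated the labelled genotypes in every library. It had 0 counts in WT 1 to WT 4, and 111, 114 and 134 counts in KO 1 to KO 3, or 2.70 ± 0.162 CPM (SD, n = 3). Against a floor of 3 counts over the WT libraries together, 0.0118 CPM, this was at least 228-fold higher in KO. Gm30783 (Entrez 102632805) lies on chromosome 14 from 22921122 to 22932356, and it was singled out after its values were seen. Its edgeR adjusted p was 0.0798, and its limma-voom adjusted p was 0.00148.

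**Figure D1:**
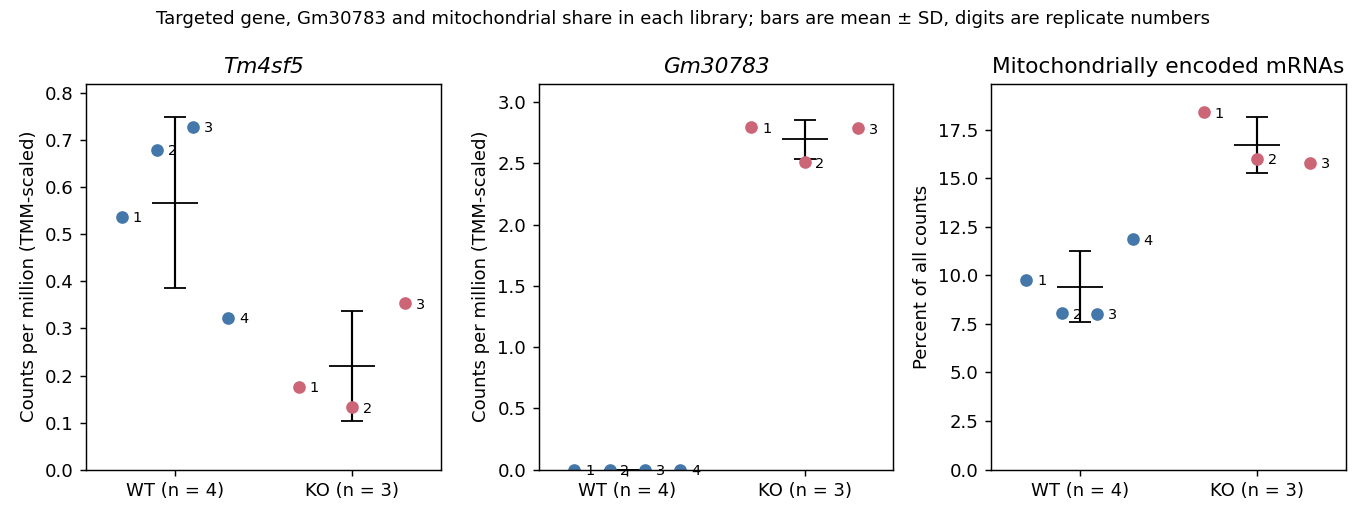
Left and middle, TMM-scaled CPM of Tm4sf5 and Gm30783 in each library; right, the percent of all counts that fell on the 13 mitochondrially encoded protein genes. Points are libraries with their replicate number, and bars are mean ± SD of 4 WT and 3 KO libraries; KO 3 lies above WT 4 for Tm4sf5, while the mitochondrial share is higher in each KO library than in any WT library.

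Across the 19185 genes tested, many genes leaned one way in KO, but no single gene passed the adjusted threshold. With edgeR, 0 genes had an adjusted p under 0.05, with or without a 2-fold change, and the smallest adjusted p was 0.0798. At an unadjusted p under 0.05 there were 4187 genes, 2363 higher and 1824 lower in KO, where chance gives 959 on average. The WT and KO values did not overlap for 3898 genes, 20.3% of those tested, and chance gives 5.71% on average. Such averages hide a wide spread, as other splits of the 7 libraries gave 89 to 3682 genes at that unadjusted p. The genes without overlap were not counted in other splits. Other tools drew the line elsewhere. DESeq2 called 1864 genes at an adjusted p under 0.05, 1002 higher and 862 lower, and limma-voom called 1, Gm30783. On simulated counts DESeq2 also called 53 unchanged genes among 173. Few genes were changed there and each was drawn independently, so that share cannot be carried over to the 1864 calls. Scaling by total counts called 1 gene, Wfdc17, and turned the split at an unadjusted p under 0.05 to 694 higher and 4871 lower. That scaling moved the median log2 fold change of all genes from -0.04 to -0.35. Without KO 1 the number at an unadjusted p under 0.05 was 2331.

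Genes of mitochondrial energy metabolism were higher in KO fat as a group. All 30 measured subunits of nuclear-encoded oxidative phosphorylation (OXPHOS) complexes rose when adjusted over the list alone, and 0 when adjusted over all genes, with a median log2 fold change of 0.85. Uqcrb, a complex III subunit, went from 117 ± 11.2 CPM (SD, n = 4) to 228 ± 51.1 CPM (SD, n = 3), a log2 fold change of 0.96 (SE 0.18, edgeR p adjusted over the list alone 0.00669). Cycs, which encodes cytochrome c, had 0.98 (SE 0.20), Ndufa4 0.97 (SE 0.20) and Ndufa10 1.02 (SE 0.21), each with that adjusted p. Of 24 measured genes of fatty acid oxidation, 22 rose and 0 fell when adjusted over the list alone, and 0 passed over all genes, with a median log2 fold change of 1.15. Acaa2 (1.37, SE 0.27), Decr1 (1.34, SE 0.23), Hadh (1.26, SE 0.24) and Eci2 (0.79, SE 0.15), all enzymes of mitochondrial β-oxidation, each had an edgeR p adjusted over the list alone of 0.005. Cpt1a (-0.43), which controls fatty acid entry into mitochondria, did not pass.

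Camera placed both lists above other genes, with adjusted p = 1.69e-16 for OXPHOS and 8.63e-13 for fatty acid oxidation. Neither call held with an estimated correlation, where the adjusted p = 0.314 for each. The OXPHOS score was 7.71 ± 0.0862 in WT (SD, n = 4) and 8.52 ± 0.406 in KO (SD, n = 3), with an exact permutation p of 0.0286. The fatty acid oxidation score was 7.38 ± 0.352 in WT and 8.43 ± 0.371 in KO, also at an exact p of 0.0286, and both scores were higher in 3 of 3 KO libraries than in any WT library. Mitochondrially encoded messages moved with these lists. They took 9.42% ± 1.82 of counts in WT (SD, n = 4) and 16.7% ± 1.44 in KO (SD, n = 3), with an exact permutation p of 0.0286. Other features of the libraries moved with them too, and are not independent of them. The 10 most abundant genes include mt-COX1, at 29860 CPM in WT and 62880 CPM in KO, so their share counts some of the same reads again. The 10 most abundant genes took 12.3% to 15.3% of counts in WT libraries and 18.4% to 24.3% in KO libraries. TMM factors were 1.10 ± 0.0464 in WT and 0.883 ± 0.0789 in KO, and genes with a count numbered 23722 to 24000 in WT libraries and 22496 to 23299 in KO libraries. With total counts alone, which moved the median of all genes from -0.04 to -0.35, the OXPHOS median was 0.50 and all 30 subunits stayed above 0. None of the 30 then passed over the list alone, and camera, which compares a list with other genes that moved under that scaling too, gave an adjusted p = 2.54e-20. In fatty acid oxidation 1 member fell without WT 2, and 1 with total counts alone.

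Glucose uptake and glycolysis genes showed a smaller shift in the same direction. Of 23 measured members, 12 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes, with a median log2 fold change of 0.63. The glycolytic enzymes Pgam1 (1.02, SE 0.23), Pfkl (1.02, SE 0.26) and Eno1 (0.93, SE 0.24), and Akt2 (0.73, SE 0.19), a kinase of insulin signalling, had an edgeR p adjusted over the list alone of 0.0246. The members that fell were transporters, Slc2a1 for glucose (-0.49, SE 0.16) and Slc16a3 for lactate (-1.16, SE 0.38). Camera gave an adjusted p = 0.000168, lost with an estimated correlation (adjusted p = 0.314), and the exact permutation p of the score was 0.0286. The counts of 12 and 2 became 0 and 0 without WT 4, without KO 1, without KO 3, without WT 2 and WT 4 together, with the replicate numbers as a block, or with total counts alone, where camera gave an adjusted p = 1.76e-05. The 2 lower genes also became 0 without WT 2 or KO 2, and 1 without WT 3.

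Of 5 lists of adipocyte and lipid genes, camera called 4 higher in KO, with fewer members past the threshold, and did not call cholesterol synthesis. None of the 4 calls held with an estimated correlation, where the adjusted p = 0.314 for each. Among 24 thermogenic genes, which mark brown and beige fat, 8 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. Their median log2 fold change was 1.48. Otop1, a proton channel, was at 37.7 ± 1.22 CPM in WT (SD, n = 4) and 2.52-fold higher in KO. Its log2 fold change was 1.33 (SE 0.17, edgeR adjusted p = 0.00115 over the list alone). The potassium channel gene Kcnk3 (0.82, SE 0.18) and the cytochrome oxidase genes Cox7a1 (1.67, SE 0.40) and Cox8b (2.14, SE 0.59) also passed. Tmem26, used as a beige fat marker, fell (-1.05, SE 0.32). Ucp1, the uncoupling protein, had 1.69 (SE 0.95) and did not pass (edgeR adjusted p = 0.145 over the list alone). Of 27 genes of fatty acid and triglyceride synthesis, 8 rose and 0 fell when adjusted over the list alone (median 0.54), among them Lpin1 (0.80, SE 0.17), Dgat1 (0.93, SE 0.20), Gpd1 (1.13, SE 0.27) and Slc25a1 (2.46-fold). Another of the 8, Mgll, encodes a lipase that breaks down monoglycerides.

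Of 20 white adipocyte markers, 2 rose over the list alone, Lipe (0.90, SE 0.22), which encodes hormone-sensitive lipase, and Fabp4 (1.13, SE 0.28), a fatty acid carrier, with a median log2 fold change of 0.55. Adrb3 (1.05, SE 0.34) and Pnpla2 (1.18, SE 0.38) did not pass. None of the 22 genes of fatty acid uptake and lipolysis passed over the list alone, with a median of 0.58. That count became 11 without WT 1, 4 without KO 3, 6 with no filter on low counts, 7 with a filter of 1 CPM in 3 libraries, 2 with the replicate block and 7 with DESeq2. Its leading members Lipe and Mgll had an edgeR p of 0.053 adjusted over the list alone, and Abhd5 (0.59) and Slc27a1 (1.32) had 0.0532. None of the 23 cholesterol synthesis genes passed either, with a median of 0.26 and Tm7sf2 (0.93) and Ebp (0.40) in the lead. Over all genes, 0 members of these 5 lists passed.

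Camera adjusted p-values were 1.6e-06 for the thermogenic list, 1.6e-06 for fatty acid and triglyceride synthesis, 1.96e-05 for uptake and lipolysis, and 0.000378 for white adipocyte markers. Exact permutation p-values were 0.0857, 0.0571, 0.0571 and 0.2. The cholesterol list was not called (camera adjusted p = 0.0744), but it passed without WT 2 (0.000984), without WT 3 (0.00337), without KO 2 (0.0393), without WT 2 and WT 4 together (0.0167), with no filter on low counts (0.0398) and with total counts alone (0.0119), where its median was -0.05. The 8 thermogenic genes became 1 without WT 2, 2 without WT 3, 15 without WT 4, 1 without KO 1, 5 without KO 3, 17 with the replicate block and 1 with total counts alone, and the 1 lower gene became 0 without WT 2, WT 3 or KO 1, with the replicate block and with total counts alone. The 8 synthesis genes became 4 without WT 1, 0 without WT 2, 5 without WT 4, 0 without KO 1, 3 with the replicate block, 3 without WT 2 and WT 4 together and 0 with total counts alone. The 2 white adipocyte genes became 6 without WT 1, 6 with DESeq2, and 0 without WT 2, WT 3, WT 4 or KO 1, or with total counts alone. With total counts alone camera gave adjusted p-values of 1.9e-11, 2.17e-08 and 2.58e-06 for the thermogenic, synthesis and white adipocyte lists.

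Macrophage markers were lower in KO fat. Of 22 measured markers, 19 fell and 0 rose when adjusted over the list alone, 0 passed over all genes, and the median log2 fold change was -1.52. Csf1r, the receptor for macrophage colony-stimulating factor, went from 235 ± 89.2 CPM (SD, n = 4) to 65.2 ± 11.4 CPM (SD, n = 3), a log2 fold change of -1.85 (SE 0.31). The complement genes C1qa (-1.45, SE 0.24) and C1qb (-1.52, SE 0.27) and Lyve1 (-1.68, SE 0.27), which marks resident macrophages and lymphatic endothelium, moved alike. The edgeR p adjusted over the list alone was 0.00254 for Csf1r, C1qa and Lyve1 and 0.00279 for C1qb. Without KO 1, 1 marker rose. The 3 markers that did not pass were Cd14 (-0.58), Cd9 (-0.06) and Lpl (0.44), of which Lpl is also an adipocyte gene. Camera gave an adjusted p = 5.89e-11, lost with an estimated correlation (adjusted p = 0.314). The score was 5.91 ± 0.482 in WT (SD, n = 4) and 4.60 ± 0.226 in KO (SD, n = 3), with an exact permutation p of 0.0571.

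Interferon response genes were lower as well. Of 22 measured genes, 15 fell and 0 rose when adjusted over the list alone, 0 passed over all genes, and the median log2 fold change was -0.84. Oas2 (-1.08, SE 0.16) and Oas1a (-1.50, SE 0.28), sensors of viral RNA, Irf7 (-0.87, SE 0.18), a regulator of interferon genes, and Usp18 (-0.93, SE 0.25), a negative regulator of interferon signalling, all passed. Camera gave an adjusted p = 7.56e-09, lost with an estimated correlation (adjusted p = 0.314), and the exact permutation p was 0.0286. The count of 15 became 5 without WT 1, 4 without WT 2, 1 without KO 1, 4 without KO 3 and 5 without WT 2 and WT 4 together.

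Lymphocyte markers leaned the same way, and the number of members that passed depended on KO 3. All 22 T cell and NK cell markers had a negative log2 fold change (median -0.54), and 0 passed over the list alone or over all genes, with Gzma (-1.28), Ncr1 (-0.95), Klrb1c (-0.97) and Foxp3 (-0.72) in the lead. Without KO 3, 21 of the 22 fell over the list alone (median -0.95), and DESeq2 gave 3. All 18 B cell markers were negative too (median -0.78), and 1 passed over the list alone and 0 over all genes: Jchain (-3.12, SE 0.62), the joining chain of secreted antibodies. Ighm (-1.07), Spib (-0.87) and Fcrla (-0.81) did not pass. Camera adjusted p-values were 7.8e-06 and 0.00642, against an adjusted p = 0.544 and an adjusted p = 0.757 with an estimated correlation, and exact permutation p-values were 0.143 and 0.286. The B cell call was lost without WT 4 (0.126), without KO 1 (0.113), without WT 2 and WT 4 together (0.842) and with total counts alone (0.154), and Jchain's count of 1 became 0 without any one of the KO libraries. Inflammatory cytokines and chemokines were not called (camera adjusted p = 0.248, 22 measured, median -0.33). Over that list alone 1 gene rose and 1 fell, the monocyte chemokine gene Ccl8 (-2.09, SE 0.31), while Il18 (-1.11) and Il1b (-1.26) did not pass and 0 passed over all genes. The count of higher genes became 0 without WT 2, WT 3, WT 4 or KO 1, and with total counts alone, and the count of lower genes became 2 without KO 3, 2 with total counts alone and 4 with DESeq2.

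**Figure D2:**
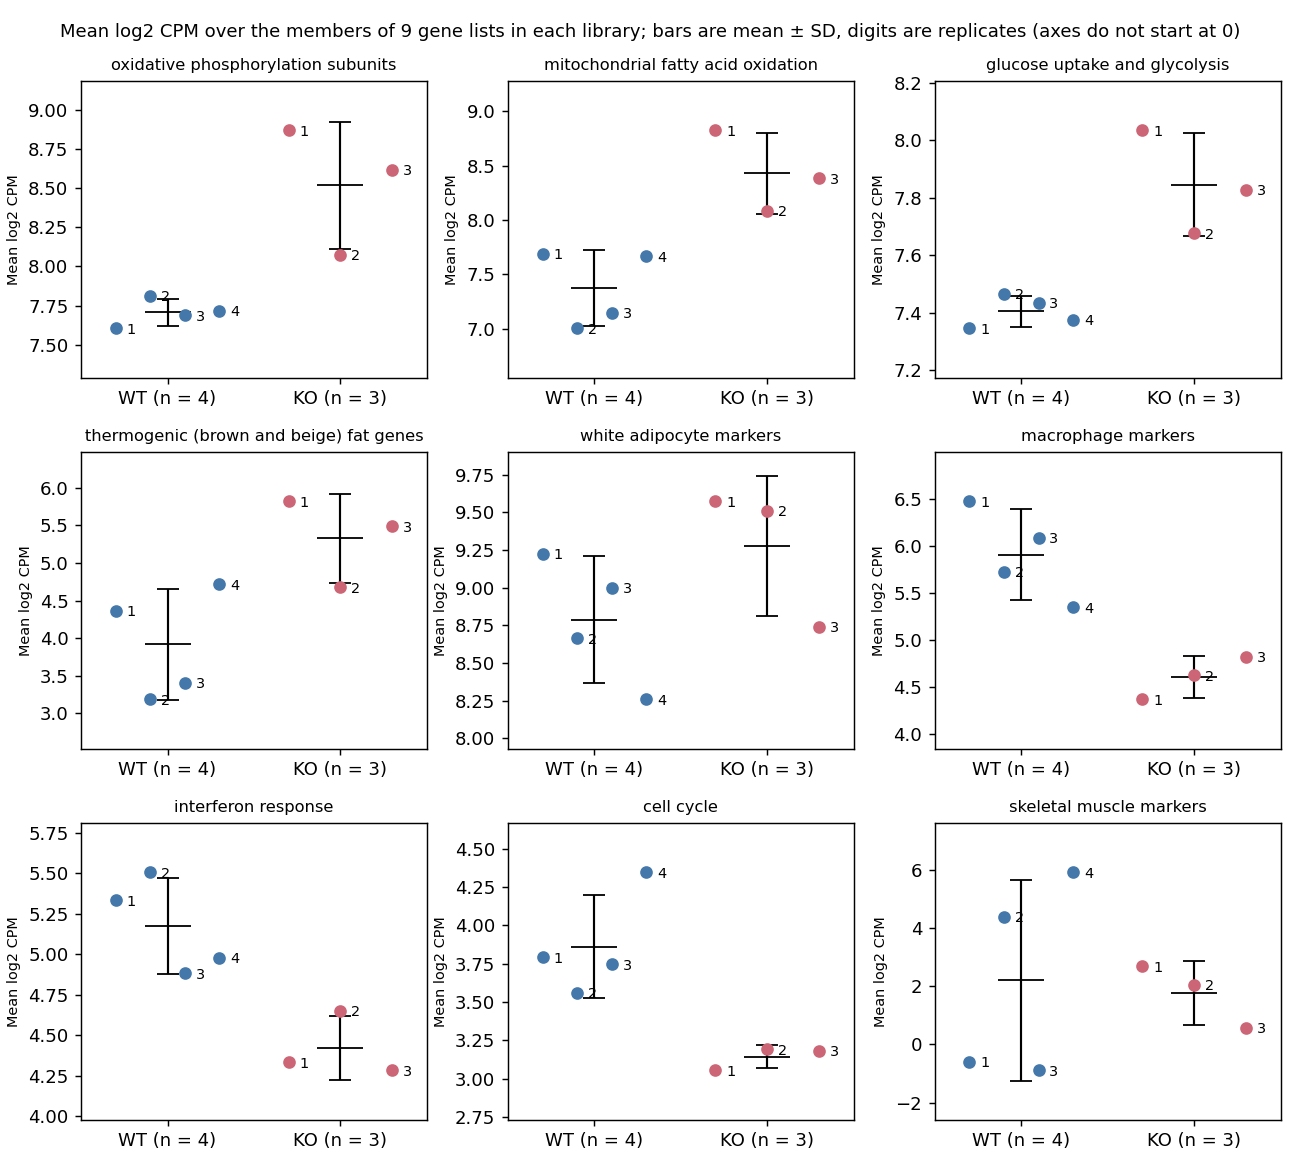
Mean log2 CPM over the members of 9 gene lists in each library, with replicate numbers, and mean ± SD of 4 WT and 3 KO libraries. OXPHOS, fatty acid oxidation and glycolysis scores are higher in every KO library than in any WT library, macrophage, interferon and cell cycle scores are lower, and skeletal muscle scores are high in WT 2 and WT 4.

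Cell cycle genes were lower in KO. Of 24 measured genes, 19 fell and 0 rose when adjusted over the list alone, 0 passed over all genes, and the median log2 fold change was -0.80. Top2a (-1.30, SE 0.29) and Aurkb (-1.11, SE 0.25), which act in mitosis, and the replication helicase genes Mcm6 (-0.78, SE 0.18) and Mcm3 (-0.83, SE 0.19) had an edgeR p adjusted over the list alone of 0.0114. Camera gave an adjusted p = 5.68e-10, lost with an estimated correlation (adjusted p = 0.314), and the exact permutation p was 0.0286. The count of 19 became 12 without KO 3, 12 without WT 2 and WT 4 together and 12 with the replicate block.

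Clock genes moved both ways. Of 18 measured, 7 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes, with a median log2 fold change of 0.69. Npas2 (-2.11, SE 0.49) and Arntl (-1.17, SE 0.37), which activate the clock's target genes, fell. Bhlhe41 (1.13, SE 0.27), Per2 (0.99, SE 0.28), Tef (1.02, SE 0.30) and Dbp (1.58, SE 0.51) were among those that rose. Camera gave an adjusted p = 0.00393, against an adjusted p = 0.359 with an estimated correlation, and the exact permutation p was 0.114. The 7 higher genes became 2 without WT 2, 0 without WT 3, 0 without KO 1, 0 without KO 2, 11 without KO 3, 1 without WT 2 and WT 4 together and 0 with total counts alone, where camera gave an adjusted p = 0.000118. The 2 lower genes became 1 without WT 2, 0 without WT 3, KO 1 or KO 2, 1 without WT 2 and WT 4 together and 1 with total counts alone.

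Stress lists were not called. Of 23 genes of the unfolded protein response, Asns (0.88, SE 0.22), an amino acid synthetase, rose and Sdf2l1 (-1.04, SE 0.21), a chaperone component, fell over the list alone, Dnajb9 (0.67) and Chac1 (1.10) did not pass, and 0 passed over all genes (camera adjusted p = 0.871). The count of higher genes became 0 without WT 1, WT 2, WT 3, KO 1 or KO 3 and with DESeq2-type size factors. It became 2 without WT 4 or KO 2 and with DESeq2. The count of lower genes became 0 without WT 2, WT 3 or KO 1. With total counts alone 0 rose and 5 fell, and with the replicate block or without WT 2 and WT 4 together 0 rose and 0 fell. None of 23 immediate early genes passed over the list alone or over all genes, with Nr4a1 (-0.70), Fosl2 (-0.57), Atf3 (-0.81) and Nr4a2 (0.40) in the lead (camera adjusted p = 0.535). Among these, 1 fell without WT 4, 1 without KO 2 and 1 with total counts alone.

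Markers of other tissues and of the stroma showed large differences between single libraries. Skeletal muscle markers had scores of 4.39 in WT 2 and 5.90 in WT 4, against -0.60 and -0.89 in WT 1 and WT 3, and 2.68, 2.04 and 0.56 in KO 1 to KO 3. None of the 20 passed over the list alone or over all genes, with a median log2 fold change of -2.58 and Myh7 (-3.46), Ttn (-2.57), Neb (-2.38) and Tnni2 (-2.94) in the lead. The list was not called (camera adjusted p = 0.354). It passed without WT 1 (0.0343) and without WT 3 (0.00787), and without WT 2 and WT 4 together it turned to higher in KO (9.33e-09), with 11 members past the threshold over the list alone. Of 12 measured epithelial markers, 0 passed over the list alone or over all genes, and Krt18 (3.67, SE 1.12), Krt8 (3.15, SE 0.97), Krt7 (1.45, SE 0.47) and Cldn4 (2.28, SE 1.17) led at under 2 CPM in either group. Camera called this list higher (adjusted p = 0.0277), against an adjusted p = 0.544 with an estimated correlation and an exact permutation p of 0.2. That call was lost without WT 2, WT 3, WT 4 or KO 1 and under a filter of 1 CPM in 3 libraries. Over the list alone 5 of 15 epithelial markers rose without KO 2, and with no filter on low counts 4 rose and 1 fell, while DESeq2 gave 6 higher and 1 lower.

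Of the remaining lists none was called. Extracellular matrix genes had a median of -0.58 over 26 members, with Tgfb1 (-0.47), Mmp14 (-1.22), Fn1 (-2.02) and Thbs1 (-1.58) in the lead and 0 past the threshold over the list alone or over all genes (camera adjusted p = 0.15). Among 20 progenitor and fibroblast markers 1 fell over the list alone and 0 over all genes, Dpp4 (-1.07, SE 0.17), which marks early adipocyte progenitors, while Icam1 (-0.52), Pdgfra (-0.91) and Dcn (-0.81) did not pass (camera adjusted p = 0.15). Both lists passed as lower in KO without WT 4 (8.01e-05 and 0.00141), without KO 1 (0.0498 and 0.0426) and without WT 2 and WT 4 together (2.31e-08 and 5.82e-05), with 11 and 6 members then past the threshold over the list alone, and with the replicate block (4.27e-05 and 0.00228). Endothelial markers (18 measured, camera adjusted p = 0.871) were led by Prox1 (-1.55), Plvap (-0.67), Pdpn (-0.72) and Flt4 (-0.47). Schwann and nerve markers (11 measured, camera adjusted p = 0.223) were led by Ngfr (-0.93), S100b (0.94) and Cdh19 (0.91), and that list passed as higher without KO 3 (0.001). Erythrocyte genes (7 measured, camera adjusted p = 0.871) included Hba-a1 (-0.30), Slc4a1 (-0.35), Alas2 (-0.16) and Hbb-bt (-0.11). None of the members of these 3 lists passed over the list alone or over all genes with all libraries. Without KO 3, 7 nerve markers rose and 1 fell, and without KO 2, 1 nerve marker rose and 1 fell, and 1 endothelial marker fell. With total counts alone 3 endothelial markers and 1 nerve marker fell, and DESeq2 gave 1 lower endothelial marker and 2 higher and 1 lower nerve markers. Signs differed between measures for 4 lists. For endothelial markers the mean was -0.02 while the median was 0.20 (-0.11 with total counts alone) and the test pointed up. For the unfolded protein response the mean was 0.02 while the median was -0.05 and the test pointed down. For immediate early genes the median was 0.0065 (-0.28 with total counts alone) while the mean was -0.05 and the test pointed down, and for erythrocyte genes the median was -0.11 and the mean -0.13 while the test pointed up.

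In all, camera called 14 of the 24 lists, 9 higher and 5 lower in KO. With an estimated correlation it called 0 (smallest adjusted p = 0.314), and fry called 0 (smallest adjusted p = 0.0518). That fry value was shared by the OXPHOS, fatty acid oxidation, glycolysis, macrophage and interferon lists. Exact permutation called 0 after adjustment (smallest 0.137), with 5 lists at an unadjusted exact p of 0.0286. No exact p can be smaller with 7 libraries, so none passes the adjustment unless many lists reach that value. The 0 of exact permutation therefore decides little. Of the 35 splits of the libraries, 12 gave 14 or more called lists, the real split included.

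**Figure D3:**
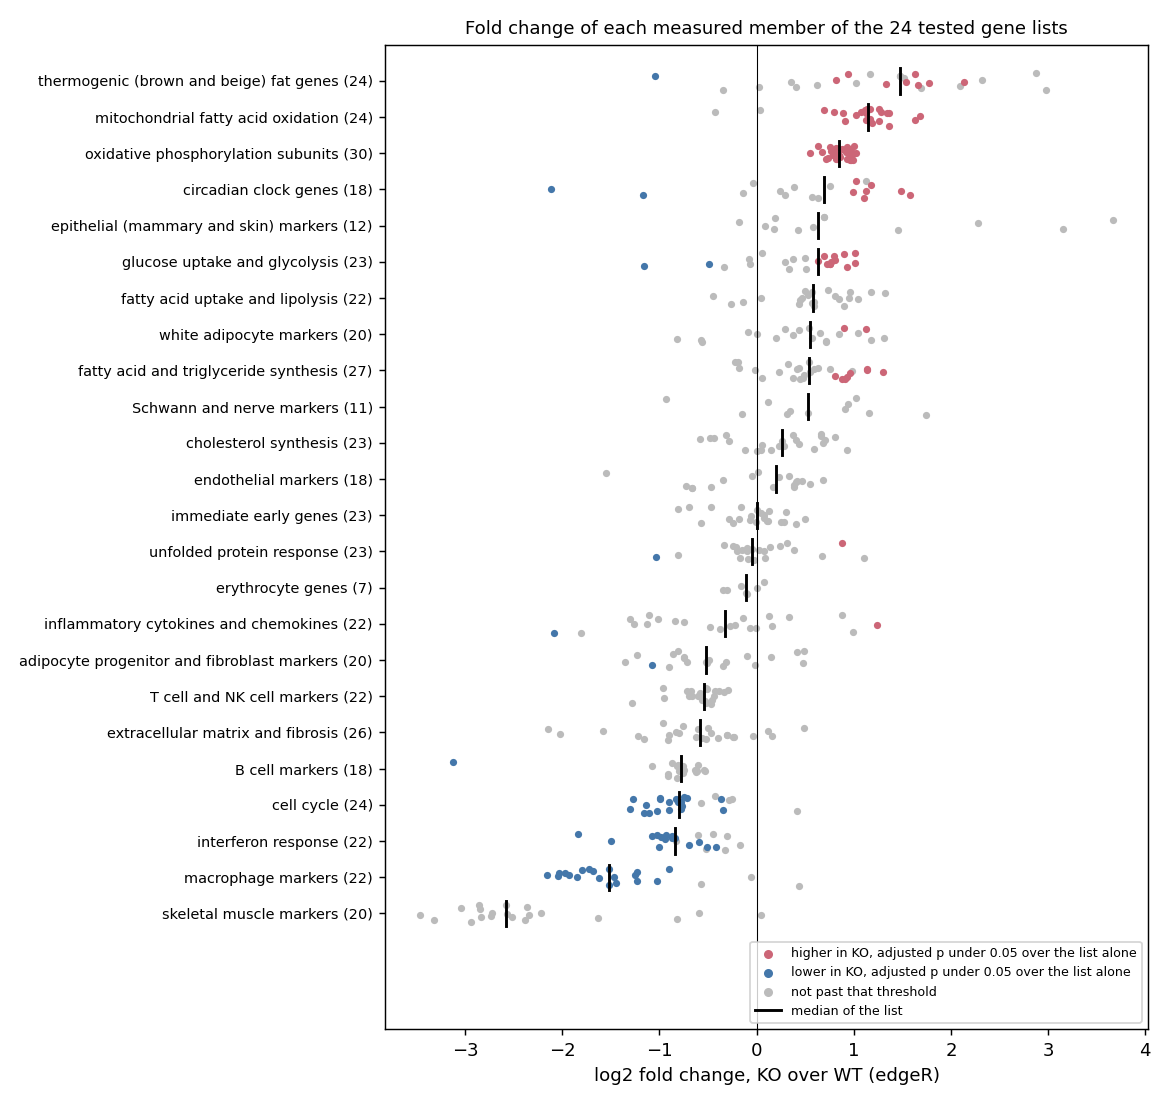
The log2 fold change of KO over WT for each measured member of the 24 tested lists, sorted by the list's median (black line); the number of measured members stands in parentheses. Coloured points have an edgeR p under 0.05 adjusted over the list alone: 30 of 30 OXPHOS subunits lie to the right and 19 of 22 macrophage markers to the left; with total counts alone 0 OXPHOS subunits pass, and the camera calls of both lists are lost with an estimated correlation (adjusted p = 0.314).

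TM4SF5 relatives and reported partners were looked at gene by gene. Of 14 measured, 0 passed over the list alone or over all genes. Slc7a1, an arginine transporter, had -0.77 (SE 0.19, edgeR p adjusted over the list alone 0.0522), Mtor 0.57 (SE 0.16, 0.0547) and Tm4sf19 -2.88 (SE 1.02, 0.0933). Sex-linked genes were read as a check of the samples. With CPM taken over total counts, without TMM scaling, Ddx3y lay between 57.4 and 120 CPM and Xist at 0.434 CPM or less in all 7 libraries. In the edgeR fit, Eif2s3y (0.32), Kdm5d (-0.30), Ddx3y (-0.11) and Uty (0.03) did not pass over the list alone or over all genes.

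Genes beside Tm4sf5 were examined because a targeted allele can carry flanking sequence of another strain. Within 10 Mb of the gene, 87 of 359 tested genes (24.2%) had an unadjusted p under 0.05, against 21.8% of other genes. The odds ratio was 1.15 (95% interval 0.89 to 1.47, Fisher's exact p = 0.273, two-sided), so no excess past the threshold was detected in that window. Within 20 Mb, 154 of 620 genes did (24.8%), with an odds ratio of 1.19 (95% interval 0.98 to 1.44, Fisher's exact p = 0.0674, two-sided). Among genes chosen after their values were seen, Alox12, a lipoxygenase gene, lies on chromosome 11 from 70241457 to 70255380, close to Tm4sf5. It was at 1.09 ± 0.160 CPM in WT (SD, n = 4) and 3.96 ± 1.34 CPM in KO (SD, n = 3), with no overlap and an edgeR adjusted p of 0.0956 over all genes. Rasd1 and Wfdc17, also singled out after their values were seen, and Ccl8 start at 59963181, 83704056 and 82115185 on chromosome 11, outside the window of 10 Mb and within that of 20 Mb.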

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

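Among the 4 WT libraries, 130 results were searched for a library far from the others, measured as its gap to the nearest other library over the whole WT range, and 4 stood apart. Chance gives about 1 in 20, or 6.5 of 130, so their number is not above chance. The number of genes with a count was lowest in WT 2, at 23722 against 23959 to 24000 in the other WT libraries (gap over range 0.853). On the log2 CPM scale, Il18 was highest in WT 4, at 4.15 against 3.11 or less (0.900). Myh7, a slow muscle myosin, was highest in WT 4, at 2.50 against -1.77 or less (0.830), and Krt18, an epithelial keratin, was highest in WT 3, at -1.24 against -3.37 or less (0.917).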

How the results depend on the processing

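Alternatives chosen after the data were seen were the omission of WT 2 and WT 4, the exact list test, the length and GC correction, the unadjusted count and its use around Tm4sf5. The count of 0 genes past the adjusted threshold became 1864 with DESeq2, 852 of them past 2-fold, 1 with limma-voom (1 past 2-fold) and 1 with total counts (1 past 2-fold). It was 0 under the other size factors, both other filters, each library left out and the block. Of the 1864 DESeq2 genes, 1857 had an edgeR p under 0.05; DESeq2 gave no adjusted p for 10604 genes. The count at an unadjusted p ran from 2331 (without KO 1) to 4636 (without KO 3) over the omissions, and the cause was not tested. Called lists ran from 13 to 18 with the preset correlation, but were 0 with an estimated correlation, 0 with fry and 0 with exact permutation. The smallest fry adjusted p was 0.0518, and 7 libraries leave exact permutation little room to pass the adjustment. Tm4sf5 ran from -1.85 to -1.07 over the omissions and never passed; a filter of 1 CPM in 3 libraries removed it. Windows of 5 and 20 Mb around Tm4sf5 gave odds ratios of 1.14 (Fisher's exact p 0.437) and 1.19 (0.0674). Fits on FPKM or TPM values and a check against a comparison by the authors were not run. Depth limits genes like Tm4sf5, with 6 to 47 counts a library.

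The replicate numbers do not pair the libraries: same-numbered deviations correlated at 0.22, -0.17 and -0.02, and not every KO library correlated best with its own number. With the numbers as a replicate block, 0 genes passed, 3263 had an unadjusted p under 0.05, 16 lists were called and Tm4sf5 had -1.62. Over the list alone the block gave 17 higher thermogenic, 3 synthesis and 0 glycolysis genes and 12 lower cell cycle genes. No KO library shares the number of WT 4, so under the block WT 4 added nothing to the KO effect. Leaving WT 4 out instead gave 15, 5, 0 and 13 for the same lists. Directions that turned under the block were Ttn (0.079), Tnni2 (0.12) and the lists of endothelial (adjusted p = 0.334), muscle (0.283), unfolded protein (0.917) and erythrocyte genes (0.631), none of them past the threshold.

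Other turned directions belonged to results not past the threshold in the fit with all libraries. With total counts, Uty turned to -0.28 and the muscle list (adjusted p = 0.484) turned up. Without WT 2 and WT 4, Ttn (1.17), Neb (0.82), Tnni2 (1.85) and the lists of muscle (9.33e-09), endothelial (0.0167) and unfolded protein genes (0.833) turned. Limma-voom turned Hba-a1 (0.034), Alas2 (0.062) and Hbb-bt (0.10), and the length and GC correction the erythrocyte list (0.796). Over single omissions the range was -0.059 to 0.11 for Uty, -0.23 to 0.029 for Ddx3y, -0.35 to 0.18 for Hbb-bt, -0.57 to 0.075 for Hba-a1, -1.78 to 0.093 for Slc4a1 and -0.42 to 0.32 for Alas2. List adjusted p-values ran from 0.161 to 0.948 for endothelial, 0.00787 to 0.948 for muscle, 0.225 to 0.959 for unfolded protein, 0.24 to 0.771 for erythrocyte, 8.01e-05 to 0.986 for matrix and 0.135 to 0.867 for immediate early genes, each turning in at least 1 omission. For all of these the cause was not tested.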

Other observations

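The tests in this part were chosen after their results were seen, except the count of splits for the number of called lists, the lymph node and thermogenic tests and the test of genes around Gm30783. The 8 further gene lists were also chosen after the data were seen, so their counts are not independent evidence. Mitochondrial and peroxisomal machinery beyond the fixed lists was higher in KO. Adjusted over the list alone, all 13 mitochondrially encoded protein genes (median log2 fold change 1.15), all 16 measured genes of the citric acid cycle (0.85), 24 of 28 mitochondrial ribosomal proteins (0.56), 11 of 16 genes of branched-chain amino acid breakdown (0.67) and 11 of 15 peroxisome biogenesis genes (0.61) rose. Over all genes 0 members of any of the 8 lists passed. Each of these scores had an exact permutation p of 0.0286. With an estimated correlation the adjusted p was 0.153 for the mitochondrially encoded, citric acid cycle and peroxisome lists and 0.193 for the other ones. All 22 cytosolic ribosomal protein genes had a negative log2 fold change (median -0.27), and 0 passed over the list alone. Camera called that list lower (adjusted p = 0.00252), lost with an estimated correlation (adjusted p = 0.496), and its exact permutation p was 0.229.

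Immune cells other than macrophages were represented by mast cell and antibody genes. Of 12 mast cell markers 7 fell over the list alone (median -2.01). The mast cell proteases Mcpt4, Cma1, Cpa3 and Tpsb2 had log2 fold changes of -2.21, -2.42, -2.64 and -2.10, while Kit (0.10) and Gata2 (0.37) lay above 0 and did not pass. Of 12 plasma cell and immunoglobulin genes 7 fell (median -2.13), and Igha (0.58) lay above 0 and did not pass. WT libraries differed widely, with Cpa3 at 15.8 ± 10.9 CPM and Ighg2b at 130 ± 204 CPM in WT (SD, n = 4). The scores of both lists had an exact p of 0.0571, and the adjusted p was 0.199 and 0.153 with an estimated correlation. Among single genes chosen after their values were seen, Tlr7, an endosomal RNA sensor, was at 28.2 ± 1.61 CPM in WT (SD, n = 4) and 7.49 ± 2.26 in KO (SD, n = 3). Wfdc17 was at 12.3 ± 1.40 and 3.31 ± 0.341 CPM, and Zfp868 at 27.3 ± 3.40 and 10.7 ± 0.580 CPM. Rasd1, a glucocorticoid-induced small GTPase, was at 58.8 ± 8.70 and 185 ± 35.8 CPM. Lars2, which can share reads with mitochondrial ribosomal RNA, was at 826 CPM in KO 1 against 118 and 80.5 CPM in KO 2 and KO 3.

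Other splits of the 7 libraries were set against the real one. For the 4187 genes at an unadjusted p under 0.05, 1 of 35 splits, the real one, gave as many, and the next highest, which set WT 1, KO 1 and KO 2 apart, gave 3682. For genes past the adjusted threshold, with or without a 2-fold change, the real count was 0, so that 35 of 35 splits had to reach it and the comparison decides nothing (highest other 1). For the 14 called lists, 12 of 35 splits gave as many and the highest other, which set WT 3, KO 1 and KO 2 apart, gave 21, so chance cannot be excluded for the number of list calls. By the number of members past the threshold over the list alone, 1 of 35 splits, the real one, gave as many for OXPHOS (30, highest other 0), fatty acid oxidation (22, 21), macrophage (19, 15), cell cycle (19, 12), interferon (15, 11), glycolysis (12, 1) and fatty acid and triglyceride synthesis (8, 2). For the thermogenic list 2 of 35 splits gave 8 or more (highest other 13) and for clock genes 3 of 35 gave 7 or more (highest other 11), so chance cannot be excluded for these. A share of 1 in 35 is the smallest that 7 libraries allow, and it was looked for in 24 lists. A single higher or lower member of the unfolded protein response also reached it (highest other 0), and the smallest exact p of the list scores after adjustment was 0.137.

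Lower macrophage markers in KO might reflect dilution by adipocyte RNA. As the whole cause it is argued against by the macrophage score less the endothelial score (-1.38), less the nerve score (-1.68) and less the mean of the endothelial, progenitor and nerve scores (-1.34), each at an exact p of 0.0286. A part stays open, since less the progenitor score it was -0.94 (exact p 0.0857) and less the matrix score -0.91 (exact p 0.171), and without WT 2 and WT 4 the progenitor, matrix and endothelial scores themselves were -0.93, -1.23 and -0.45 (smallest exact p possible 0.1). Without those 2 libraries the macrophage score was -1.23 less the endothelial and -1.83 less the nerve score (exact p 0.2 each). It was -0.74 less the progenitor score (exact p 0.4) and -0.44 less the matrix score (exact p 0.6). The test of less lymph node tissue is limited. The macrophage difference was -1.50 (SE 0.31, exact p 0.0286) with the B cell score as covariate, against -1.30 without it. But the macrophage score fell as the B cell score rose across WT libraries, and rose with it across KO libraries, so 1 common slope describes neither group. At like B cell scores, 4.88 in WT 1 and 4.76 in KO 1, the macrophage scores were 6.47 and 4.37, which argues against this cause for those 2 libraries only. A loss of macrophages or a lower expression of their genes in KO animals stays open as a hypothesis, limited by the estimated-correlation p of 0.314 and the exact p of 0.0571 for the score alone.

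Higher OXPHOS genes in KO are argued not to be a length or GC effect, since the score difference was 0.71 after that correction (exact p 0.0286) against 0.81 before it. A larger share of adipocyte RNA stays open in part: the OXPHOS score less the white adipocyte score differed by 0.32 (exact p 0.486). That difference assumes an equal rise of both scores. Yet WT 1 had the highest white adipocyte score in WT (9.23) and the lowest OXPHOS score (7.60). At like white adipocyte scores, 8.66 in WT 2 and 8.74 in KO 3, the OXPHOS scores were 7.81 and 8.62. This argues against adipocyte share as the whole cause for that pair only. KO 1 and KO 2 (9.57 and 9.51) lay above every WT library in white adipocyte score, so it stays open there. More thermogenic adipocytes stay open too. With the thermogenic score as a covariate the KO effect on the OXPHOS score was 0.59 (SE 0.32, exact p 0.171), and 7 libraries leave too wide an error. The OXPHOS score also rose with the thermogenic score across KO libraries but not across WT libraries, so 1 common slope describes the groups poorly. A response of adipocytes to the loss of Tm4sf5 may add to these and was not tested separately.

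Gm30783 could be counted in KO libraries alone because of an allele carried along with the targeted region, but it lies on chromosome 14 and Tm4sf5 on chromosome 11. A haplotype around Gm30783 that differs between the colonies could also shift some of its neighbours. Within 5 Mb, 16 of 85 tested genes (18.8%) had an unadjusted p under 0.05, against 21.8% of others, with an odds ratio of 0.83 (95% interval 0.45 to 1.45, Fisher's exact p 0.599). No excess was detected, but a haplotype need not change the expression of most genes in it. This count therefore does not exclude such a haplotype. A variant that reaches Gm30783 alone, such as a small insertion or deletion, and a change caused by the loss of Tm4sf5 were not tested and stay open.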
